A study of Homo sapiens with 6 samples.

How the data were processed

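Expression was measured in H358, an established human bronchioalveolar carcinoma cell line, in 6 samples hybridised to 1-colour arrays, 1 array for each of the 6 conditions. Per the labels' protocols, RNA was extracted with Trizol, amplified by an Eberwine-based method to amino-allyl antisense RNA and coupled to the dye Cy5. The authors deposited linear probe intensities from which background had been subtracted, since between 10 and 1146 probes per array lay below 0. Every positive deposited intensity up to 10000 was a whole multiple of a step of its own array, within a tolerance of 0.02, so whole-number signals had been multiplied by 1 factor per array. The scanner, the background method, the target of the scaling and any averaging of spots are not given in the sources used here, and the table holds no detection flags. The median intensity per array ran from 335.2 to 398.1.

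The table held 28264 probes. Of these, 25893 carried 1 gene in the platform annotation, 0 carried several and 2371 were unnamed. All 25893 gene identifiers matched the RefSeq gene table, which was used for current symbols only, and they stood for 19090 genes. No coordinates are given. Of 321 genes in the gene lists, 14 were not analysed here because no probe carried them and 53 fell below the filter on dim probes.

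Values below 0 were set to 0, a pseudocount of 16 was added and log2 was taken. The dimmest 40% of the named probes by mean over the 6 arrays were left out, and the probe with the highest mean stood for its gene, which left 12350 genes. Fold changes are therefore on the log2(intensity + 16) scale, which understates the change of dim genes. The additive model of treatment and line was fitted with limma 3.58.1 (lmFit and eBayes) in R 4.3.3, with Benjamini-Hochberg adjustment at 0.05. It leaves 2 residual degrees of freedom, to which the prior added 34.3, and assumes that the line difference is the same under the 3 treatments. No condition was repeated, so the difference between lines in the response to a cytokine had no test: genes were counted by size, with a signed difference of at least 1 on the log2 scale and a response of at least 1 in either line.

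The 16 gene lists and the rule for the genes named were fixed before the data were examined. A list with at least 5 measured members was tested with camera at a preset correlation of 0.01. Each call was also read with the correlation estimated per list. That setting rests on the 2 residual degrees of freedom, so a call lost with it does not show that correlation between genes undid it. The endothelial list had 4 measured members, none of which passed the test in any comparison. For single pairs of arrays, the median of a list was placed among those of 10000 random lists of the same size matched on mean level. The rule named the 10 genes with the largest positive and the 10 with the largest negative mean difference per tested comparison, among those past the threshold with the same sign in every pair, filled by size where fewer passed; 12 genes fixed by name, of which BIRC3 was not analysed here; up to 4 members of each list with the largest absolute difference; and the 8 genes per direction with the largest difference in response between lines. For the difference in response, the members of each list were ranked after subtracting the median of all genes. Of the 10 genes most raised between the lines, 1 is not described.

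The additive fit was tested on simulated data with 200 changed genes among 12350. For the line difference it recovered 88% of changes of 1 on the log2 scale with 5 false calls; for IL-1b it recovered 55% with 5 false calls, and for TNFa 70% with 4. Changes of 2 were recovered in 100% of cases for each of these comparisons, with 3, 14 and 17 false calls. The simulated noise met the model's assumptions, with changes equal in every pair and no jump on 1 array. These figures are therefore a best case and not the error rate of the calls below. The placement among random lists was tested on 200 simulated lists of 20 genes: 1.5% of unchanged lists and 92.5% of lists lowered by 0.5 fell under the bound of 2.5%. Alternatives were quantile normalization, centring each array on its median, no filter on dim probes or 60% left out, the mean of all probes of a gene, pseudocounts of 1 and 64, eBayes with a trend and robust estimation, fits without the covariate, fits on fewer arrays and other size limits. Leaving out each array in turn, and leaving out probes whose signal on 1 array lay over 3 log2 units from all 5 others, were chosen after seeing the data. For the line difference, leaving out either array of a pair gave the same fit, so such fits count each pair once per array. For a cytokine response, leaving out either array of the other cytokine gave the same fit and left the mean unchanged. The tests of explanations for induced genes were read against a bootstrap over genes at the start. Random lists took its place, and the verdicts were the same. Both treat genes as independent: random lists do not carry the correlation within a co-regulated set, so a placement among them can look too extreme. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.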

Results

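Gene expression was profiled in an H358 line carrying GFP, labelled as the control, and in an H358 line labelled as expressing YAP(5SA), a form of the Hippo pathway coactivator YAP whose inhibitory phosphorylation sites are mutated. Each line received vehicle, IL-1b or TNFa for 60 min before harvest, which gave 6 arrays. The series title sets the question: which genes respond to YAP when these inflammatory cytokines are present. The labels write the cytokine dose as 10 g/ml, a unit that cannot be meant as written, so the dose is taken as unknown. Median intensities were 379.2 and 335.2 in the vehicle arrays of the GFP and YAP(5SA) lines, 398.1 and 343.5 with IL-1b, and 340.7 and 366.3 with TNFa. There were no replicate arrays: the line difference was seen in 3 pairs of arrays and each cytokine response in 2 pairs. Nothing states that the pairs came from separate cultures, and p-values do not measure a spread between replicates. They measure how far the line difference varied between treatments, pooled with a prior from all genes. That prior supplied 34.3 degrees of freedom against 2 from the gene itself, so the SE of most genes lies near the prior. Their small number limits the precision. With 1 line of each kind, the line difference includes whatever else differed between the 2 lines.

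The targeted gene did not read higher in the line labelled YAP(5SA). The probe for YAP1 gave log2 levels of 12.91, 12.88 and 12.46 in the GFP line under vehicle, IL-1b and TNFa, and 11.67, 12.31 and 12.08 in the line labelled YAP(5SA). The mean difference was -0.73 ± 0.21 (limma SE, 3 pairs, adjusted p = 0.0120), and the call was lost in 4 of the 6 fits that left out an array. Leaving out either array of a pair gave the same fit. Those 4 fits are the ones without the vehicle pair (-0.48) and without the IL-1b pair (-0.81), each counted once per array. The position of this probe in the transcript is not known here, so it may not see a transgene and checks nothing about the label. The line is called by its label below.

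**Figure D1:**
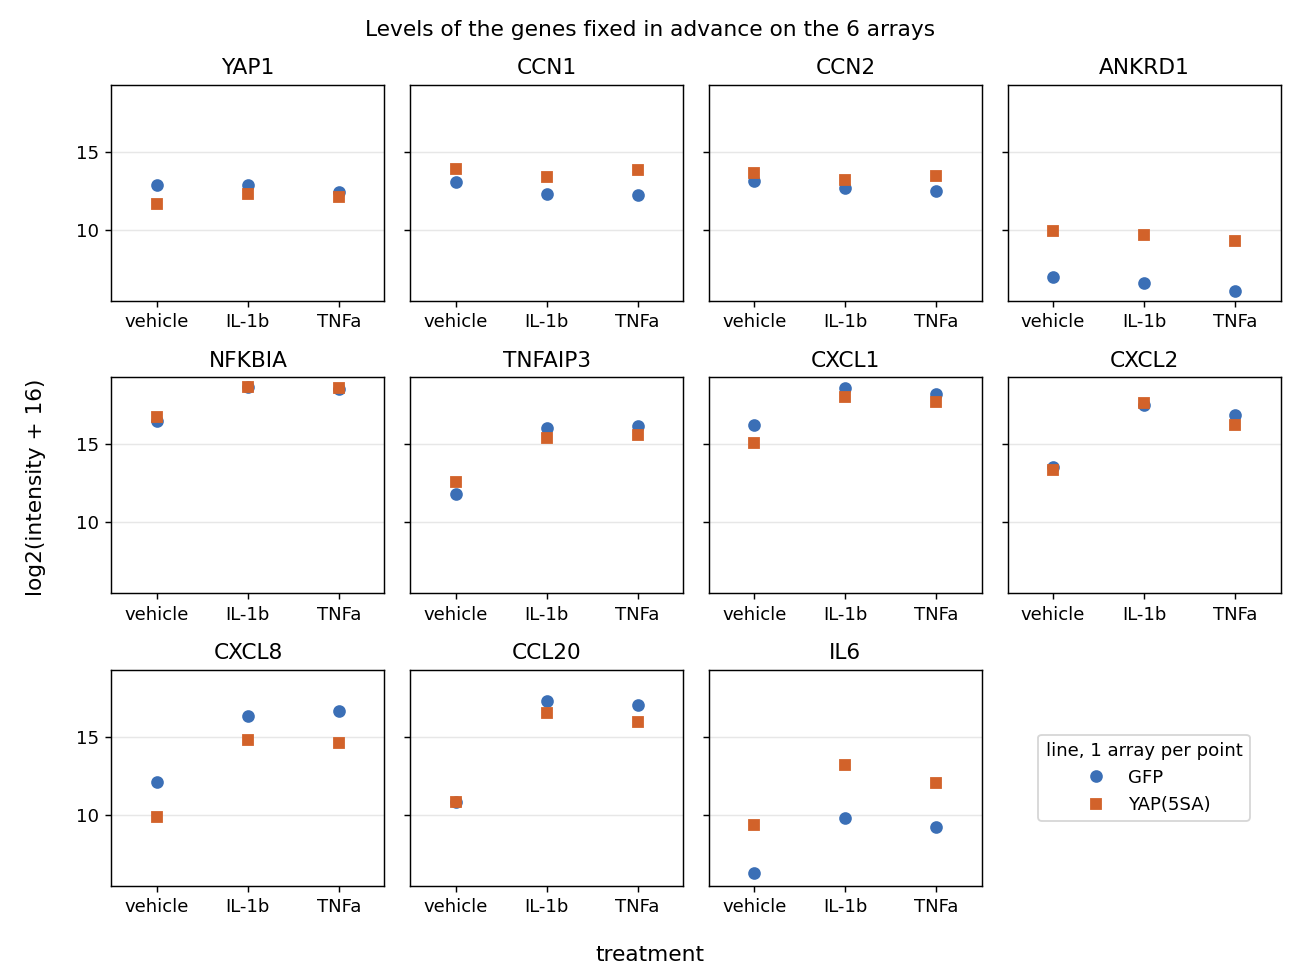
Log2(intensity + 16) of the 11 measured genes fixed by name, by treatment, with 1 array per point (circles, GFP line; squares, line labelled YAP(5SA)). ANKRD1 and IL6 lie higher in the line labelled YAP(5SA) under every treatment, CXCL8 lies lower, and the 7 cytokine-responsive genes in the lower rows lie higher with either cytokine than with vehicle.

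Known YAP target genes rose in the line labelled YAP(5SA), among them ANKRD1, AXL and the matricellular CCN1 and CCN2. Interferon-induced antiviral genes such as IFI27, MX1 and OAS2 fell together. Genes of the cytoskeleton and of mesenchymal cells rose in part, and chemokine genes divided, with CCL5 and IL6 higher and CCL2 and CXCL8 lower. Of 24 measured targets, 18 rose and 0 fell (19 rose when adjusted over the list alone), with a median log2 difference of 0.78. ANKRD1, a cardiac ankyrin repeat protein used as a YAP reporter gene, rose by 3.09 ± 0.20 (SE, 3 pairs, adjusted p = 4.9e-15). The receptor tyrosine kinase AXL rose by 2.02 and LATS2, a kinase that inhibits YAP, by 1.68. CCN1 and CCN2 rose by 1.16 and 0.68; the call of CCN2 was lost in 4 of the 6 fits that left out an array and with no filter on dim probes. Camera gave an adjusted p of 3.1e-12 for the list, and an adjusted p = 0.232 with an estimated correlation. Among Hippo pathway components, 5 of 16 rose, among them FRMD6 (2.18), WWC1 (1.21) and TEAD1 (0.88), and 2 fell, TEAD2 (-0.97) and YAP1 (camera adjusted p = 0.0208; adjusted p = 0.504 with an estimated correlation). The counts adjusted over the list alone were the same, 5 and 2.

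Interferon-induced genes fell together in the line labelled YAP(5SA). Of 22 measured, 18 fell and 0 rose (18 and 1 when adjusted over the list alone), with a median of -1.53. The differences were -5.96 for IFI27, -3.48 for the pro-apoptotic factor XAF1, -3.35 for IFI44L and -3.03 for the antiviral oligoadenylate synthetase OAS2. The list's median was -1.58, -1.58 and -1.47 in the vehicle, IL-1b and TNFa pairs. Camera gave an adjusted p of 1.3e-21, and an adjusted p = 0.232 with an estimated correlation.

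Some cytoskeletal and mesenchymal genes rose, while most members of these lists did not pass the test. Of 17 cytoskeletal genes 5 rose and 0 fell, also when adjusted over the list alone, led by the actin-binding LIMA1 (3.42). Of 14 mesenchymal genes 6 rose and 1 fell (7 and 1 when adjusted over the list alone), among them TAGLN, a smooth muscle actin-binding protein (1.76), N-cadherin CDH2 (1.14), PDGFRB (1.10) and ZEB2 (1.02). E-cadherin CDH1, an epithelial gene, also rose (1.65), while EPCAM fell (-1.03); of 10 epithelial and alveolar genes 4 rose and 2 fell (6 and 2 when adjusted over the list alone; camera adjusted p = 0.0705). Of 12 hypoxia and glycolysis genes 4 rose and 1 fell (5 and 1 when adjusted over the list alone), including the hexokinase HK2 (1.07). Camera adjusted p was 0.0111 for the cytoskeletal list and 0.0208 for the mesenchymal and hypoxia lists; each call was lost with an estimated correlation (adjusted p = 0.504). The mesenchymal call was also lost with no filter on dim probes (adjusted p = 0.0958).

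Inflammatory genes differed between the lines in both directions. Of 21 chemokines and cytokines, 4 rose and 9 fell in the line labelled YAP(5SA) (6 and 11 when adjusted over the list alone; camera adjusted p = 0.314). CCL5 rose by 3.39 and IL6 by 3.12, whereas the monocyte attractant CCL2 (-1.99) and the neutrophil attractant CXCL8 (-1.95) fell. Of 20 genes of NF-kB feedback and response, 2 rose and 7 fell (2 and 9 when adjusted over the list alone), with the cyclooxygenase PTGS2 lower by the largest amount of its list (-4.04) and BCL3 at -1.38 (camera adjusted p = 0.0208; adjusted p = 0.504 with an estimated correlation). With no filter on dim probes its adjusted p was 0.163. The list's median difference was -0.09 under vehicle (29.6th percentile of matched random lists), -0.50 under IL-1b and -0.35 under TNFa, so it lay below random lists on the cytokine arrays alone. Of 16 cytokine receptor and signalling genes 0 rose and 5 fell, among them MAP3K8 (-1.52) and IL1R1, the receptor of IL-1b (-1.25), with the same counts when adjusted over the list alone (camera adjusted p = 0.225). Immediate early genes split 4 up and 6 down of 20 (4 and 7 when adjusted over the list alone; camera adjusted p = 0.436).

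The single genes with the largest differences included secreted proteins such as CHRDL1, NTS and MMP7. CHRDL1, a BMP antagonist, was higher by 6.04 ± 0.21; also among the largest were JPH1 (5.39), TENM2 (5.07), MFAP5 (4.73), SHISA2 (4.37), KISS1 (4.28), AMPH (4.25), PLAC8 (4.17) and DUSP22 (4.03). Neurotensin, NTS, fell by 7.59 ± 0.21, with AGR2 (-7.40), the metalloproteinase MMP7 (-7.12), CEACAM6 (-7.01), the glutathione peroxidase GPX2 (-6.83), THSD7A (-6.59), TCIM (-6.15), AKR1C1 (-5.15) and INHBB (-5.07). In all, 976 genes were higher and 1101 lower of 12350 (408 and 499 by at least 2-fold), and 2042 of these 2077 had the same sign in all 3 pairs. Centring each array on its median gave 1430 higher and 964 lower, so the share that was higher depends on the scaling. Without the IL-1b pair 1023 genes were called.

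Camera called none of the remaining lists between the lines. Of 25 cell cycle genes 1 rose, FOXM1 (1.06; 2.22 under vehicle, 0.36 under IL-1b and 0.60 under TNFa), and 0 fell (1 and 0 when adjusted over the list alone; camera adjusted p = 0.294). Of 17 stress genes 4 rose, led by SESN2 (1.75), and 1 fell (4 and 2 when adjusted over the list alone; camera adjusted p = 0.417). Of 7 leukocyte genes 1 fell, CD14 (-1.61), also when adjusted over the list alone (camera adjusted p = 0.183). Of 10 housekeeping genes none passed the test, also when adjusted over the list alone (camera adjusted p = 0.616).

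**Figure D2:**
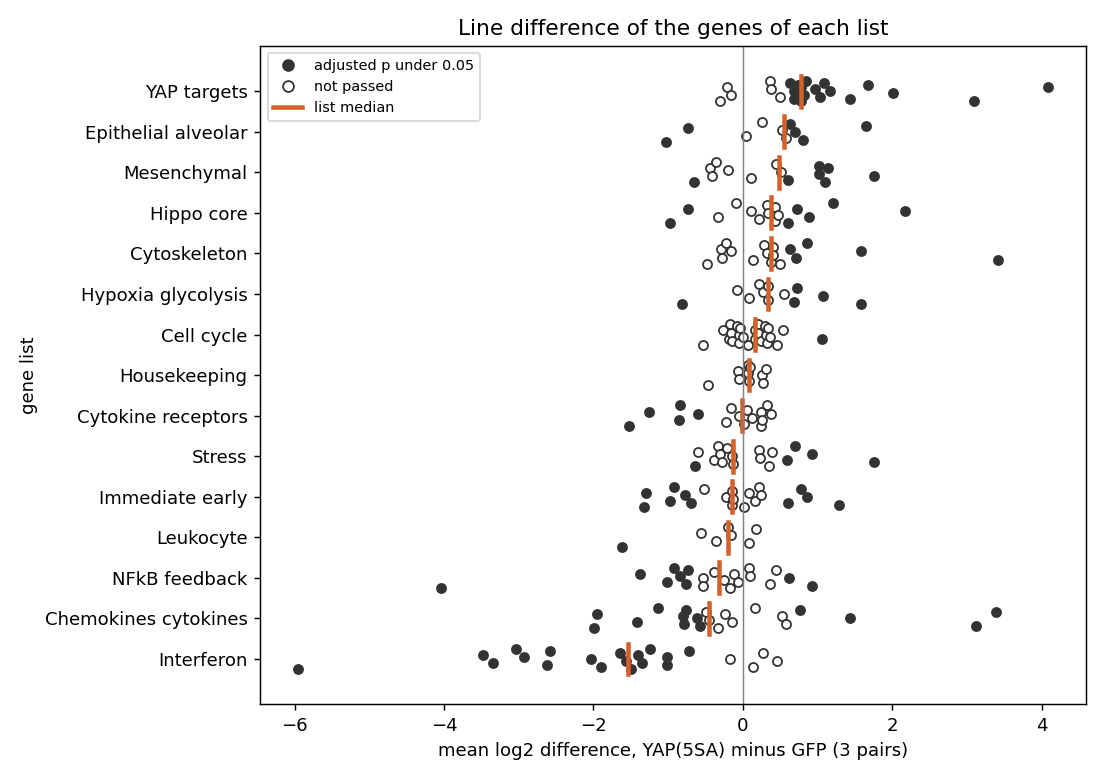
Mean log2 difference between the line labelled YAP(5SA) and the GFP line over 3 pairs, for each measured gene of 15 lists (points; filled, adjusted p under 0.05) with the list median (bar). YAP targets lie highest, with a median of 0.78, and interferon genes lowest, with a median of -1.53.

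IL-1b raised chemokine and cytokine genes such as CCL20, CXCL8 and TNF in both lines. Feedback inhibitors of NF-kB, the main transcription factor downstream of the IL-1 receptor, rose with them, and so did immediate early genes such as FOSB and EGR1. CCL20, an attractant of dendritic and T cells, rose by 6.07 ± 0.27 (SE, 2 pairs, adjusted p = 2.4e-19), TNF by 5.63, CXCL3 by 4.69, CXCL8 by 4.59, CXCL2 by 4.16 and IL6 by 3.70. Of 21 chemokines and cytokines 12 rose and 0 fell (13 when adjusted over the list alone). Of 20 NF-kB feedback and response genes 13 rose (16 when adjusted over the list alone), including the deubiquitinase TNFAIP3 (3.55), NFKBIZ (2.56), the ribonuclease ZC3H12A (2.37) and the NF-kB inhibitor NFKBIA (2.05). Of 20 immediate early genes 13 rose (14 when adjusted over the list alone), with FOSB at 2.91, the mRNA decay factor ZFP36 at 2.78 and EGR1 at 2.10. Camera adjusted p was 1.3e-41, 6.9e-30 and 8.9e-24 for these lists. With an estimated correlation the camera adjusted p was 0.0656, 0.172 and 0.387, and the calls were lost. The estimate for chemokines and cytokines was -0.015, below the preset 0.01, so correlation between genes does not account for the loss of that call.

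YAP targets did not move as a list under IL-1b. Of 24 measured, 1 rose, the kinase NUAK2 (0.96), and 0 fell (2 and 1 when adjusted over the list alone; camera adjusted p = 0.795). CCN1, CCN2 and ANKRD1 gave -0.62, -0.46 and -0.30, none of which passed the test. Among 25 cell cycle genes 1 fell, FOXM1, by 1.09, which was -0.16 in the GFP line and -2.02 in the line labelled YAP(5SA) (camera adjusted p = 0.0322; adjusted p = 0.387 with an estimated correlation and 0.0760 with no filter on dim probes; 1 fell when adjusted over the list alone). Among 16 cytokine receptor and signalling genes MAP3K8 (2.01) and IRAK2 (1.00) rose (2 when adjusted over the list alone). DDIT4 (1.03) rose among 17 stress genes (1 when adjusted over the list alone), and the B cell gene MS4A1 (1.11) among 7 leukocyte genes (2 when adjusted over the list alone). In the Hippo, cytoskeletal, mesenchymal, epithelial, interferon, hypoxia and housekeeping lists no gene passed the test over all genes, and camera called none of them; adjusted over the list alone, 1 epithelial gene rose and 1 hypoxia gene fell.

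With IL-1b, 163 genes were called higher and 129 lower (limma, adjusted p under 0.05), and 286 of these 292 had the same sign in both pairs. The named genes include probes that jumped on 1 array. CLDND1, called higher at 4.16, was low only on the YAP(5SA) vehicle array, and E4F1, DEDD, CLEC19A and TMEM43, called lower, each rested on 1 array. C1QBP, a mitochondrial matrix protein, gave 9.08, a value set by the pseudocount because the vehicle readings are near the floor of the scale: its only probe read 4.37 and 5.24 on the vehicle arrays and 13.57 to 14.01 on the other 4. IFFO2 changed by -4.77, from 13.61 and 12.50 to 8.08 and 8.47, and IZUMO3 by -3.92, each through a single probe. The rule for a jump on 1 array does not cover changes shared by a pair of arrays, so a fault of these probes was not tested. Also called were LINC03025 (3.61), PFKP (-2.35), VASN (-1.46), STC2 (-1.41) and TIGD5 (-1.30). PFKP changed by -4.45 in the GFP pair and -0.24 in the other, and without the GFP IL-1b array its mean was -0.74 and the call was lost. The calls of VASN and TIGD5 were lost in 3 and that of STC2 in 2 of the 6 fits that left out an array. The count of calls was 478 (161 higher, 317 lower) without the GFP vehicle array, 107 without the YAP(5SA) vehicle array, 58 without the GFP IL-1b array, 71 without the YAP(5SA) IL-1b array and 692 without either TNFa array. Of 22 named calls, 13 held in all 6 such fits.

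TNFa raised chemokine and cytokine genes in both lines, as IL-1b did, with CCL20, TNF and CXCL8 at the top. NF-kB feedback genes such as TNFAIP3, which ends signalling by removing ubiquitin, rose too. YAP targets did not move as a list. CCL20 rose by 5.69 ± 0.27 (SE, 2 pairs, adjusted p = 2.2e-18), TNF by 4.78, CXCL8 by 4.62, CXCL3 by 3.83, TNFAIP3 by 3.69, the pattern recognition protein PTX3 by 3.15, CXCL2 by 3.10 and IL6 by 2.85. Of 21 chemokines and cytokines 10 rose and 0 fell (13 when adjusted over the list alone; camera adjusted p = 3.2e-77). This was the only list call of the 17 in all tested comparisons that held with an estimated correlation (adjusted p = 0.0350). Of 20 NF-kB genes 11 rose (16 when adjusted over the list alone), among them IRF1 (2.47) and PTGS2 (2.03); with an estimated correlation the adjusted p was 0.0916. Of 20 immediate early genes 8 rose (11 when adjusted over the list alone), among them ZFP36 (2.30) and FOSB (2.21); with an estimated correlation the adjusted p was 0.392. Of 24 YAP targets 0 passed the test over all genes (2 rose and 1 fell when adjusted over the list alone), and ANKRD1 gave -0.74.

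With TNFa 85 genes were called higher and 10 lower, and 90 of these 95 had the same sign in both pairs. MAP3K8 (1.79) rose among the signalling genes (2 when adjusted over the list alone) and MS4A1 (1.08) among the leukocyte genes (1 when adjusted over the list alone). Camera called the leukocyte list higher (adjusted p = 0.00453). The call was lost with an estimated correlation (camera adjusted p = 0.711) and with no filter on dim probes (camera adjusted p = 0.310). The list's median response was 0.68 in the YAP(5SA) pair, with 7 of 7 genes above 0. In the GFP pair it was -0.20, with 3 of 7 above 0, at the 48.8th percentile of matched random lists, so that pair does not show the rise. The cell cycle factor FOXM1 (-1.32, the 1 call among 25 cell cycle genes, also when adjusted over the list alone), ID1, an inhibitor of basic helix-loop-helix factors (-1.06), AGR2 (-1.09) and RTL10 (-0.99) fell, but the calls were lost in 2, 4, 4 and 5 of the 6 fits that left out an array, and those of FOXM1, ID1 and AGR2 also with quantile normalization and with median centring. FOXM1 changed by -0.51 in the GFP pair and -2.12 in the YAP(5SA) pair. Its line, IL-1b and TNFa calls thus all rest largely on a high reading on the YAP(5SA) vehicle array. Of 23 named calls with TNFa, 12 held in all 6 fits. C1QBP (8.91, again against readings near the floor) and IFFO2 (-5.18) changed as with IL-1b, on the same vehicle arrays. Each of these genes was read by a single probe. The rule for jumps looks for a change on 1 array, so it cannot flag a fault shared by both vehicle arrays. Such a fault and a cytokine response were not told apart. Of the 20 genes named by size, 7 had a jump on 1 array: CLDND1, KNTC1, PANK4, CAMKK2, ATXN7L3B, CCT7 and CLEC19A. Without the GFP vehicle array 50 genes were called. In the other lists no gene passed the test, over all genes or over the list alone.

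Many genes were raised by both cytokines, most of the chemokines above among them. Those that also differed between the lines were mostly lower in the line labelled YAP(5SA), such as CXCL8 and PTGS2, with IL6 and PTX3 as exceptions. Of 163 and 85 genes called higher, 67 were shared, against 1.12 for independent lists and a mean of 0.1 in 20 simulations of unchanged genes with shared simulated vehicle arrays. With no changed gene and no jump on 1 array, those simulations could give hardly any calls, so their count does not weigh the part of the shared vehicle arrays. Across genes, which are not independent replicates, the mean responses correlated at r = 0.599, against 0.501 in the simulation, with a covariance of 0.0813 against 0.0332. Between responses that share no array the correlation was 0.566 for IL-1b in the GFP line with TNFa in the line labelled YAP(5SA), and -0.111 for IL-1b in the line labelled YAP(5SA) with TNFa in the GFP line. Each of these rests on 1 vehicle array per response, and part of the overlap may come from the shared vehicle arrays. Of the 67 shared genes, 31 were also lower in the line labelled YAP(5SA), 7 were higher and 29 were not called between lines. The genes that were lower included CXCL8, CXCL3, PTGS2, TNF, CCL20, CCL2 and the acute phase gene SERPINA3 (-2.79), the last named after its values were seen. TNF (6.63 and 6.76 in the GFP line and the line labelled YAP(5SA)) and CCL20 (10.81 and 10.82) were not lower under vehicle. Nor were EGR1 (12.92 and 13.60), LINC03025 (5.87 and 6.24), NFKBID (7.36 and 7.64) and PNRC1 (9.31 and 9.32), also among the 31. The CCL20 call was lost in 4 of the 6 fits that left out an array, and with median centring, no filter on dim probes, the mean of all probes or a pseudocount of 1. Those that were higher included IL6, PTX3 (1.83), SLC27A1 and SSTR5; the other 3, DHX29, TUT1 and BLM, were low on the GFP vehicle array alone. Of the 31 that were lower, CLDND1, LAX1, P3H1, KNTC1 and TMEM156 were low on the YAP(5SA) vehicle array alone, which by itself places a gene in both sets. Genes lower in the line labelled YAP(5SA) overlapped with those raised by IL-1b in 47 cases against 14.5 for independent lists (Fisher's exact test, two-sided p = 1.6e-13) and with those raised by TNFa in 34 against 7.58 (p = 8.8e-15, Fisher's exact test). These comparisons share arrays, and genes are not independent.

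Few genes passed the test between IL-1b and TNFa, and their number depended on single arrays. None of the known cytokine targets, such as CXCL2 or the immediate early gene FOS, passed the test between them. The comparison called 2 genes higher with IL-1b, CAMKK2 (3.60) and ATXN7L3B (3.06), both low on the YAP(5SA) TNFa array alone, and 1 lower, IZUMO3 (-3.17). CXCL2 (1.06), FOS (1.23) and IL23A (1.10) were higher with IL-1b in both lines but did not pass the test, nor did CCL4 (1.01), LRRK1 (1.51), ANP32E (-1.25) and HNRNPH2 (-1.25). Immediate early genes as a list had a median of 0.41 (camera adjusted p = 0.0312) and chemokines and cytokines of 0.21 (camera adjusted p = 0.0490), with 0 genes of either list past the threshold over all genes and 1 and 6 higher when adjusted over the list alone; with an estimated correlation the adjusted p was 0.997 for both. The chemokine and cytokine call was also lost with quantile normalization (adjusted p = 0.110) and with no filter on dim probes (adjusted p = 0.382). The median of all genes was 0.22 higher with IL-1b in the GFP line and -0.02 in the line labelled YAP(5SA). At an unadjusted p under 0.05 limma gave 1533 genes. Quantile normalization and median centring each left 0 higher and 1 lower, whereas eBayes with trend and robust estimation gave 9 higher and 123 lower. Leaving out 1 array gave 9 to 503 calls, and leaving out probes with a jump on 1 array gave 34.

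Immediate early and NF-kB genes responded less to IL-1b in the line labelled YAP(5SA), in values with no test. EGR1, a growth factor-induced transcription factor, and the feedback genes TNFAIP3 and NFKBIZ rose less there with either cytokine, whereas CXCL8 and CXCL1 rose at least as much. The chemokine CXCL10 rose in the GFP pair, by 1.63 with IL-1b and 1.93 with TNFa. In the YAP(5SA) pair its changes were -0.28 and 0.10. After IL-1b, EGR1 rose by 3.28 on the log2 scale in the GFP pair and 0.92 in the YAP(5SA) pair, FOSB by 3.86 and 1.97, TNFAIP3 by 4.26 and 2.83, NFKBIZ by 3.27 and 1.85, TNF by 6.32 and 4.94, and the adhesion molecule ICAM1 by 2.35 and 0.97. After TNFa the pairs were 2.91 and 0.92 for EGR1, 4.37 and 3.01 for TNFAIP3, 2.72 and 1.05 for NFKBIZ, and 1.89 and 0.48 for ICAM1. CXCL8 responded by 4.23 and 4.96 to IL-1b and by 4.52 and 4.72 to TNFa, CXCL1 by 2.38 and 2.92 and by 1.97 and 2.59, and IL6 by 3.51 and 3.89 and by 2.95 and 2.74. A dimmer CXCL1 probe gave larger responses, 3.37 and 4.16 to IL-1b and 2.52 and 3.29 to TNFa. Single housekeeping genes also differed in response between the lines: YWHAZ by 0.78 and TFRC by -0.74 with IL-1b, and YWHAZ by 0.92 and HPRT1 by -0.87 with TNFa. All 20 immediate early genes had the lower IL-1b response in the line labelled YAP(5SA), with a median difference of -0.72, under all 10000 matched random lists. For NF-kB genes the median difference was -0.46, with 5 of 20 above 0. Random lists draw genes independently, whereas the correlation within the immediate early list was estimated at 0.746, so this placement can look too extreme. Chemokines and cytokines had a median of -0.30 with IL-1b (0.68th percentile, 8 of 21 above 0), with IL1A at -2.10 and CXCL10 at -1.91. With TNFa the medians were -0.32 for immediate early genes (6 of 20 above 0), -0.23 for NF-kB genes (7 of 20) and 0.07 for chemokines and cytokines (11 of 21), against an all-gene median of 0.26. Immediate early genes were already higher on the YAP(5SA) vehicle array, by a median of 0.36 (99.99th percentile); the line difference was -0.51 on the IL-1b arrays (0.03rd percentile) and -0.03 on the TNFa arrays (6.06th percentile). For YAP targets the median difference was 0.17 with IL-1b, at the 89.8th percentile, and 0.32 with TNFa, at the 64.1st.

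As signed differences of at least 1, the change with IL-1b was more positive in the line labelled YAP(5SA) for 38 genes and more negative for 168, and the change with TNFa more positive for 136 and more negative for 59. A more negative value holds genes that rose less and genes that fell more: with IL-1b, 485 genes fell at least 2-fold in the YAP(5SA) pair and 37 in the GFP pair, while 169 and 217 rose. The 485 rest on 1 array against 1. The YAP(5SA) IL-1b array was also at least 2-fold below the YAP(5SA) TNFa array in 183 genes and above it in 13. Probes below 0 numbered 10 on the vehicle, 596 on the IL-1b and 1146 on the TNFa array of that line. Whether IL-1b or the arrays lowered these genes was not tested. Over all genes the TNFa difference had a median of 0.26, and quantile normalization turned its counts to 62 more positive and 105 more negative, median centring to 56 and 124. Relative to that median, EGR1 stood at -2.25, ICAM1 at -1.68 and TNFAIP3 at -1.62 with TNFa. Of the 16 genes named by size per cytokine, 12 with IL-1b and 14 with TNFa had a jump on 1 array, such as CLDND1 and DHX29. The others with IL-1b were PFKP (4.21), EXOSC8 (-3.43), EVC (-2.59) and ICAM4 (-2.58), and with TNFa TRPC5 (2.59) and ENO3 (-3.60). EXOSC8 too changed mainly on 1 array. EVC was low on the GFP vehicle array alone (7.60, against 8.86 to 9.74) and TRPC5 on the YAP(5SA) vehicle array alone (6.82, against 8.39 to 9.29). PFKP was low on the GFP IL-1b array (11.61) and less so on the GFP TNFa array (14.10), against 16.06 on the GFP vehicle array.

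**Figure D3:**
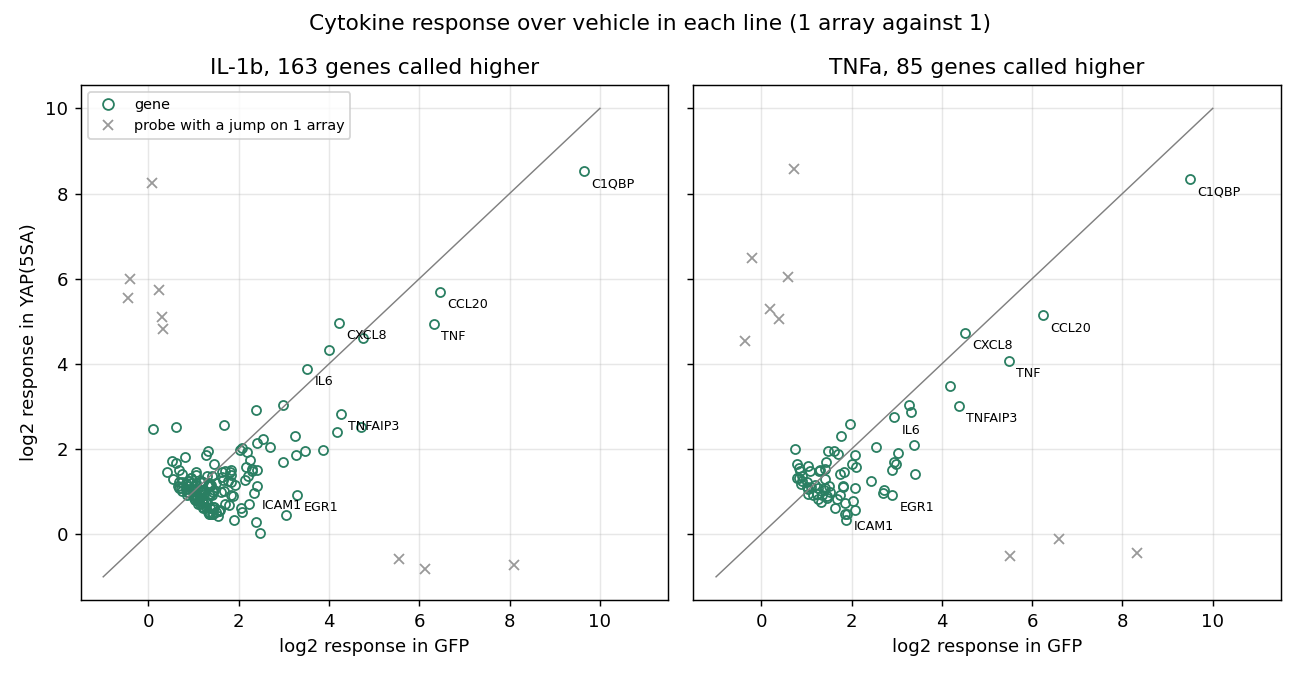
Log2 response to IL-1b (left) and TNFa (right) in the line labelled YAP(5SA) against that in the GFP line, 1 array against 1, for the 163 and 85 genes called higher; the line marks equal responses and crosses are probes with a jump on 1 array. TNFAIP3, TNF, EGR1 and ICAM1 lie below the line of equality and CXCL8 on or above it.

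Within each treatment, the line difference reached 2-fold in similar numbers of genes. YAP targets were higher in the line labelled YAP(5SA) with and without cytokine, and interferon genes lower. There were 455 higher and 612 lower under vehicle, 412 and 746 under IL-1b, and 648 and 513 under TNFa. Median centring gave 636 and 456 under vehicle and 611 and 493 under IL-1b, and quantile normalization 512 and 585 under IL-1b, so the direction of the excess depends on the scaling. The median line difference of YAP targets was 0.66, 0.84 and 0.92 under vehicle, IL-1b and TNFa, above all 10000 matched random lists each time.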

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

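The tests in this part were chosen after the results were seen. No condition had replicates, and the differences listed here were not tested. Among named genes without a jump on 1 array, 16 differences had opposite signs in the compared pairs, each pair at least 0.5 from 0 on the log2 scale. The line difference went from above 0 under vehicle to below 0 with a cytokine for EGR1 (change -2.36 with IL-1b and -1.98 with TNFa), TNFAIP3 (-1.44 and -1.36), NFKBIZ (-1.41 and -1.67), EGR3 (-1.56 with IL-1b) and IZUMO3 (-1.67 with IL-1b). It went from below 0 to above 0 for NKG7 (1.21 with IL-1b), MYD88 (1.13 with TNFa) and MMP2 (1.65 with TNFa). The response itself had opposite signs in the GFP line and the line labelled YAP(5SA) for FOSL1 with IL-1b (difference -1.40) and, with TNFa, for DDIT3 (-1.10), HSPA1A (1.26), MMP2 (1.65) and VWF (1.36). The limit of 0.5 was set on values as deposited. The all-gene median line difference was -0.10 under vehicle, -0.07 with IL-1b and 0.17 with TNFa. For the TNFa response it was -0.19 in the GFP line and 0.09 in the line labelled YAP(5SA). Relative to these medians, NKG7, MYD88, MMP2, HSPA1A and VWF would not meet the limit, nor would NFKBIZ with IL-1b. Their flags may therefore reflect shifts of whole arrays.

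Probes without a gene name entered no comparison. Of 1239 such probes above the filter on dim probes, 6 were at least 2-fold above vehicle in both lines with IL-1b and 3 with TNFa, and 0 were as far below it with either.

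The genes called higher with a cytokine rose less in the line labelled YAP(5SA), by a median of -0.29 for 163 genes with IL-1b and -0.35 for 85 with TNFa (-0.61 relative to all genes, -0.56 after quantile normalization and -0.62 after median centring). The single scale factor per array does not account for it: after quantile normalization the median still lay -0.32 from that of matched random lists for IL-1b, the cytokine with the smaller gap, under all 10000 of them. Nor does saturated signal account for it, since among genes below log2 14 on every array the gap to random lists was -0.35 for the same cytokine. The vehicle arrays are not the whole of it either, because on the cytokine arrays themselves these genes were lower in the line labelled YAP(5SA) by -0.16 relative to random lists with IL-1b, though the vehicle arrays carry a part of similar size: there the same genes had a median of 0.06 against -0.11 for random lists (99.97th percentile). A weaker or earlier-ending induction in the line labelled YAP(5SA) may account for the pattern, but with 1 array per condition a difference between these cultures in handling or timing stays open and untested.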

How the results depend on the processing

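Counts of calls depended on few arrays. The line difference gave 2394 calls after median centring (1430 higher), 1383 with 60% of probes left out, and 1023 to 2300 when 1 pair or 1 array was left out. IL-1b gave 58 calls with no filter on dim probes, 80 with the mean of all probes, 455 with trend and robust estimation, 4 without the covariate, 692 on the 4 arrays compared, and 58 to 692 leaving out 1 array, with 478 and a turned direction without the GFP vehicle array. TNFa gave 36, 45 and 3 calls with no filter, the mean of probes and no covariate, and 50 to 129 leaving out 1 array. IL-1b against TNFa gave 1 call with quantile normalization, 1 with median centring, 2 with no filter, 44 with 60% left out, 1 with the mean of probes, 1 with a pseudocount of 1, 16 with 64, 132 with trend and robust estimation, 0 without the covariate, 63 on the 4 arrays compared, 34 without probes with a jump, and 9 to 503 leaving out 1 array (63 without either vehicle array, 9 and 18 without the GFP or YAP(5SA) IL-1b array, 20 and 503 without the GFP or YAP(5SA) TNFa array). The cause was not tested.

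For the size-counted differences in response, IL-1b gave 621 with no filter, 130 with 60% left out, 1731 at 1.5-fold and 34 at 3-fold. TNFa gave 167 with quantile normalization, 180 with median centring, 805 with no filter and 33 at 3-fold, each with more negative than positive differences, and 101 with 60% left out and 2242 at 1.5-fold. Line differences within vehicle gave 1092 after centring, 672 with 60% left out, 2957 at 1.5-fold and 439 at 3-fold; within IL-1b 1104 after centring, 1817 with no filter, 688 with 60% left out, 3129 and 426; within TNFa 1789, 745, 3455 and 443. A stricter filter tests fewer genes and a size limit sets its own count; otherwise the cause was not tested. Of 17 list calls 1 held with an estimated correlation, 16 with quantile normalization and 12 with no filter.

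Of the line calls, 1990 of 2077 kept their direction and call after quantile normalization, as did 258 of 292 for IL-1b and 76 of 95 for TNFa. Of 587 values of the 87 named results under 7 planned settings, 515 stayed on the same side of the threshold, 71 lost their call and 1, CAMKK2 in IL-1b against TNFa, changed sign (-0.0942 with a pseudocount of 1). Of the named line calls 24 of 28 held in every fit without 1 array; CCL20, CCN2, CXCL1 and YAP1 did not. Line and treatment enter the fit together, so the arrays are already paired in it. With no detection flags, signal over background is not known, and dim genes are the least certain.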

Other observations

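The tests of the spot jumps and of the scaling in this part were chosen after the results were seen; the test on taste receptor, beta-defensin, PRAMEF and LCE genes was set out before its result was seen. Several of the largest line differences rest on 1 of several probes. Dimmer probes of MFAP5 and NTS differed in the same direction as the probes used, with the lower line near the floor, and another probe of AKR1C1 differed by -4.32 in the vehicle pair, less than the probe used (-5.04). Other probes of CHRDL1, JPH1 and SHISA2 lay near the floor on all 6 arrays, and a second probe of THSD7A differed by -0.82 in the vehicle pair.

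Of the 10 ways to split the 6 arrays 3 against 3, the split by line gave 2077 calls and was the only one with as many. The highest of the others gave 5. In those splits the line difference enters the residual of the fit, which by itself leaves few calls, so their counts do not show what unchanged genes would give. With 10 splits no share under 0.05 can be reached.

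On 28 probes the signal of 1 array lay over 3 log2 units from all 5 others, 20 below and 8 above. A defect of the spot is a candidate explanation: of 10 other probes, past a limit on mean level, for 8 of these genes, 0 moved over 1 log2 unit on that array in the same direction. Of the 17 jump probes that entered the comparisons, this check covers only those of CAMKK2, CCT7 and KIF5B. Probes with a jump made up 16 of 2077 line calls, 13 of 292 IL-1b calls and 14 of 95 TNFa calls. No biological explanation was tested, and a change in a transcript form that only 1 probe reads stays open.

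As deposited, the signed change with TNFa was more positive in the line labelled YAP(5SA) for 69.7% of the genes counted by size, which does not say in which line more genes responded. After quantile normalization the share was 37.1%. That step removes most of the all-gene shift of 0.26: random lists matched to the induced genes then had a median of 0.07. It therefore lowers this share whatever caused the shift, and it does not decide whether the authors' single scale factor per array did. The all-gene correlation between the lines was 0.546 for the IL-1b response and 0.0479 for the TNFa response. Of 12 gene families screened after quantile normalization, olfactory receptors (119 genes, median 0.37) and keratin-associated proteins (28 genes, 0.52) stood far above matched random lists, which raised unspecific signal on the arrays as an explanation. Genes with LINC or LOC names (111 genes, median 0.26, 99.88th percentile) lay above random lists too, while NDUF genes (42 genes, -0.21, 0.59th percentile) lay below them and mitoribosomal genes (75 genes, -0.08) stood at the 2.53rd percentile. In 23 taste receptor, beta-defensin, PRAMEF and LCE genes, not used in that screen, the median lay at the 88.3rd percentile, which does not decide it. A biological difference between the lines in the TNFa response was not tested.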
